A study of Rattus norvegicus with 10 samples.

How the data were processed

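Whole kidneys were dissected from male Sprague-Dawley rats with free access to water (control, 5 animals) or after 72 hours without water (dehydrated, 5 animals), and polyadenylated RNA was sequenced as 1 library per animal, per the labels. The deposited counts are unnormalised fragment counts per Ensembl gene. They were made by the authors with featureCounts 1.6.2 on paired-end, trimmed and Rsubread-aligned reads, with reverse-strand counting (setting 2) and the Ensembl release 103 annotation of Rnor 6.0, per the file headers. The version and settings of the aligner and the trimming tool are not given in the sources used here. The table holds 32623 genes, with the summed exonic length of each gene in bp. Because counting used strand, fragments of overlapping genes on opposite strands were told apart, but genes that overlap on 1 strand or share near-identical sequence can lose or exchange fragments, and counts of such genes are uncertain.

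The authors also deposited a table of their comparison, made with DESeq2 per the submitters' processing notes; its version and design formula are not given in the sources used here. It holds log2 fold changes with their standard errors on the log2 scale, p-values and adjusted p-values, and, for each library, a normalised signal, which is the deposited count divided by 1 size factor per library. The table lists genes with a mean normalised count of at least 8.00, and 601 of its 15284 genes have no adjusted p-value. Its values were used only to describe the authors' comparison. Of its 10 columns of normalised signal, the 2 named for the replicates numbered 6 each hold the counts of the library whose name carries the other letter. The letters of these 2 columns fit the titled groups, and those of the library names do not.

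Samples were grouped by title and treatment label, which agree for all 10 libraries. For the replicates numbered 6 the library name carries the letter of the other group, so both alternatives, leaving out and exchanging the 2 libraries, were planned. Replicate libraries of a group were compared before averaging: the chi-square per degree of freedom over tested genes was 13.3 to 32.0 in the 20 pairs, so no 2 libraries agreed within counting noise. Comparisons were made in R 4.3.3.

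The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest) on the deposited counts, with TMM scaling, no covariate and the genes kept by filterByExpr (minimum count 10, minimum total 15), which left 15047 of the 21311 genes with any count. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Log2 fold changes are dehydrated over control. The SE of a log2 fold change was taken as its absolute value divided by the square root of the quasi-likelihood F. CPM values, the counts relative to the library's total over tested genes, were scaled by TMM. Principal components and correlations used log2 CPM with a prior count of 2. Single values per library were compared by exact two-sided permutation over 252 assignments, whose smallest p is 0.0079. Exon ranges are the distinct annotated exon intervals of a gene over its transcripts. Among libraries, 3 counts correspond to 0.084 to 0.10 CPM, and no tested gene was at 0 in every library of a group.

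The test was run on simulated counts drawn from the means and library sizes of the dehydrated against control comparison, with 14952 genes tested. Changes were planted only in genes with a mean of at least 2 CPM. At a true change of 1.5-fold, 58 of 67 changed genes (86.6%) were called, at 2-fold 67 of 67 and at 4-fold 66 of 66. In the same run 7 unchanged genes were called. The median change of genes called in the real data, 1.38-fold, is below the smallest simulated change. Recovery of such changes, and of changes in lower genes, was not simulated. With no change simulated, 1 gene was called. The counts were drawn without correlation between genes, from the dispersions that edgeR estimated. Both runs thus follow the model under test and do not give the rate of false calls in real data. Far fewer genes were changed in the simulation than were called in the real data. The neighbour count was also tested on simulated data over the 15047 tested genes of this comparison: with the calls placed at random, 56 neighbours shared a direction against a permuted mean of 54.4, and with 100 pairs planted, 176 against 74.7. Precision is set by the spread between 5 animals per group; intervals and floors from counts would cover counting error only.

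The design, alternatives, gene lists and rule for named genes were fixed before the data were examined. The rule took the genes with the largest and smallest log2 fold change among called genes with a mean of at least 2 CPM and a symbol. The reference table used here (assembly GRCr8) pairs 0 of the Ensembl identifiers with a symbol. The symbol condition was therefore dropped and the rule limited to 2 genes that rose and 2 that fell, and 42 planned lists of kidney pathways and cell type markers were not analysed here. The genes named in the rule by symbol, such as renin and the aquaporins, were likewise not analysed here.

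The alternatives were DESeq2 size factors in the edgeR fit, no filter on low counts, the DESeq2 1.42.0 Wald test, limma 3.58.1 voom with sample quality weights, the replicate number as a block, leaving out each library, leaving out or exchanging the libraries numbered 6, an adjusted p below 0.1 and a change above 2-fold. The exchange under DESeq2 and limma was added after the data were seen. Calls of neighbouring genes were compared with 10000 permutations of calls among tested genes of the same chromosome and expression decile. Neighbours are tested genes with consecutive start positions on a chromosome.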

Results

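Whole kidneys of male Sprague-Dawley rats, an outbred laboratory strain, were compared after free access to water and after 3 days (72 hours) without water, with the stated purpose of finding genes of osmoregulation. Polyadenylated RNA of whole kidney from 10 separate animals was sequenced, 5 control rats and 5 dehydrated rats. Assigned fragments per library ranged from 29454213 to 35898689. The mean was 32673579 ± 2139292 in control and 32826957 ± 2564500 in dehydrated libraries (SD, n = 5), a difference within the spread between animals (exact two-sided permutation test, p = 0.913). The number of genes with at least 1 fragment was 18421 ± 109 in control and 18401 ± 235 in dehydrated kidneys (SD, n = 5; exact permutation p = 0.889). Of the genes with counts, the most abundant took between 1.47% and 2.71% of the fragments of a library. None of the 37 annotated mitochondrial genes had counts, nor had any gene on the end of chromosome 19 or on chromosomes 20, X and Y. These totals and shares leave out all 2817 genes of this part.

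Water restriction changed the abundance of 1275 of 15047 tested kidney genes, 707 of them higher and 568 lower in dehydrated rats. Most changes were small: the median change among the 1275 genes was 1.38-fold, and 687 of them (53.9%) changed by less than 0.5 on the log2 scale. More than 2-fold changes were found for 213 genes, 113 higher and 100 lower. The genes that rose together held 5.06% ± 0.19 of the fragments of tested genes in control and 7.22% ± 0.37 in dehydrated kidneys (SD, n = 5). The genes that fell held 6.93% ± 0.29 in control and 5.11% ± 0.077 in dehydrated kidneys (SD, n = 5). These shares are given without a test, since the genes were selected on the same libraries. The calls come from edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p below 0.05, and 3213 genes had an unadjusted p below 0.05. For 946 of the 1275 genes the 5 dehydrated kidneys lay entirely above or entirely below the 5 control kidneys. Such separation was found for 7.87% of all tested genes, against 0.794% by chance.

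The titles and treatment labels define the groups, but the library names of the replicates numbered 6 carry the letter of the other group. With both of these libraries exchanged between the groups, 0 genes passed the edgeR threshold and 1654 had an unadjusted p below 0.05, while DESeq2 called 71 genes and limma 3. If the titled groups are right, the exchange mixes the treatments within each group, and a loss of calls follows by construction. A score on genes called from the other 8 libraries set -1 at the control mean and 1 at the dehydrated mean. Control replicate 6 scored -0.879 and dehydrated replicate 6 scored 0.937, each on the side of its titled group. Without both libraries, 896 genes were called (461 higher, 435 lower), and without control replicate 4 the genes called lower numbered 378.

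**Figure D1:**
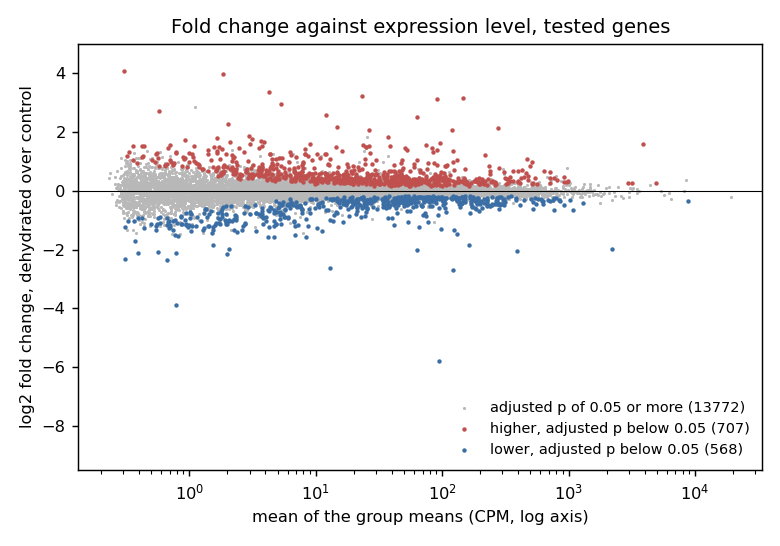
Each point is 1 of the 15047 tested genes, with the mean of the control and dehydrated group means in CPM on a log horizontal axis and the log2 fold change, dehydrated over control, on the vertical axis. The 707 red points (higher) and 568 blue points (lower) passed an adjusted p of 0.05, and most of them lie within 1 log2 unit of 0.

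The dominant axis of variation between kidneys separated the treatments. The first principal component of log2 CPM carried 32.0% of the variance, with scores from -23.2 to -8.53 in control and from 11.8 to 21.7 in dehydrated kidneys. The group means differed (exact two-sided permutation test, p = 0.0079, n = 5 per group, the smallest p this design can give). The second component carried 12.1%. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.989 to 0.993 between kidneys of the same group and 0.983 to 0.989 between kidneys of different groups.

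**Figure D2:**
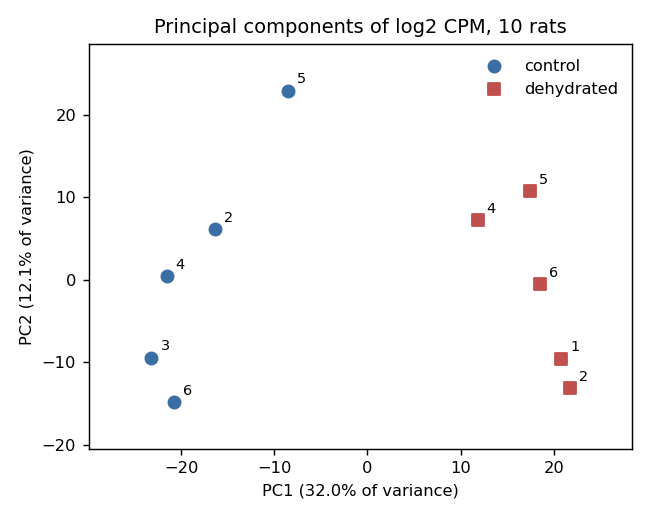
Scores of the 10 kidneys on the first (horizontal) and second (vertical) principal components of log2 CPM, with the share of variance on each axis. Circles are control and squares dehydrated rats, and numbers are replicate numbers; all control kidneys lie below 0 and all dehydrated kidneys above 0 on the first component.

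Among called genes with a mean of at least 2 CPM, the genes with the largest changes differed between the groups by 6.51-fold to 54.8-fold. Gene symbols are not paired with the Ensembl identifiers in the tables used here, so 2 genes that rose and 2 that fell are given by identifier, with their positions in rat assembly Rnor_6.0. ENSRNOG00000013552 (chromosome 1, 264160129 to 264172729, minus strand, 6 annotated exon ranges) fell most, from 187 ± 92.0 CPM in control to 3.41 ± 1.88 CPM in dehydrated kidneys (SD, n = 5). Its log2 fold change was -5.78 (SE 0.45, edgeR adjusted p = 9.1e-06), a 54.8-fold difference, and its control values ranged from 74.7 to 267 CPM. ENSRNOG00000008915 (chromosome 6, 127075954 to 127127413, minus strand, 5 exon ranges) fell from 212 ± 90.0 to 32.4 ± 10.5 CPM (SD, n = 5), a log2 fold change of -2.70 (SE 0.28, edgeR adjusted p = 0.0001). ENSRNOG00000015992 (chromosome 9, 88918433 to 88921001, plus strand, 4 exon ranges) rose from 0.748 ± 0.277 to 7.83 ± 2.99 CPM (SD, n = 5), a log2 fold change of 3.38 (SE 0.28, edgeR adjusted p = 1.4e-05). ENSRNOG00000003616 (chromosome 13, 92894431 to 92988137, minus strand, 2 exon ranges) rose from 4.54 ± 2.01 to 42.3 ± 7.39 CPM (SD, n = 5), a log2 fold change of 3.22 (SE 0.23, edgeR adjusted p = 5.1e-06). For each of the 4 genes every dehydrated kidney lay outside the control range. The calls of all 4 were lost when the libraries numbered 6 were exchanged between the groups. If the titled groups are right, that exchange mixes the treatments within each group. The loss then follows by construction and does not show that the calls are fragile.

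**Figure D3:**
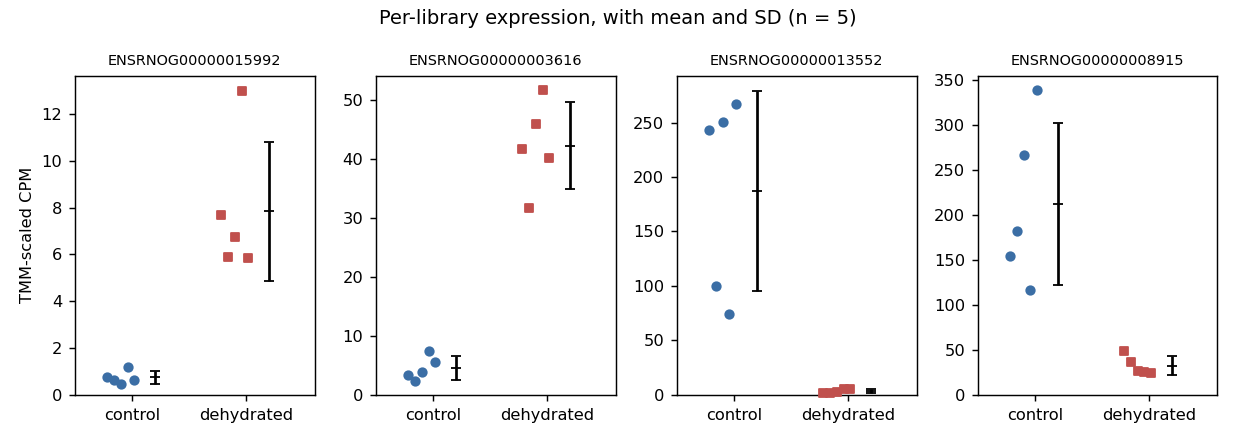
Expression of 4 genes in each kidney, in CPM scaled by TMM on linear vertical axes, for control (circles) and dehydrated (squares) rats. The black bars show the mean and SD of 5 kidneys; the values of ENSRNOG00000013552 lie between 74.7 and 267 CPM in control and between 1.51 and 5.67 CPM in dehydrated kidneys.

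Change was also found among the most abundant of the tested genes, which leave out the mitochondrially encoded ones. Of the 89 tested genes with a mean of at least 1000 CPM, 9 were called, 4 higher and 5 lower. This share is near the 8.47% called among all tested genes. Of the 9 genes, 2 changed more than 2-fold, and both were singled out after their values were seen. A gene on chromosome 3 (171213936 to 171219871, plus strand, 10 exon ranges) rose from 1948 ± 118 to 5846 ± 1643 CPM (SD, n = 5), a 3.00-fold difference (edgeR adjusted p = 7.6e-05). Another gene on chromosome 3 (114711562 to 114728410, minus strand, 9 exon ranges) fell from 3514 ± 647 to 893 ± 98.4 CPM (SD, n = 5), a 3.93-fold difference (edgeR adjusted p = 1.1e-06).

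Called genes were found at every level of expression and on each of the 19 autosomes with tested genes. Among the 3762 genes with the highest mean CPM (56.7 CPM or more), 10.7% were called, 196 higher and 205 lower, against 7.28% of the 3761 genes with the lowest mean CPM, 149 higher and 125 lower. The share did not rise steadily with expression: it was 8.45% from 4.42 to 20.3 CPM and 7.50% from 20.3 to 56.6 CPM, the latter below that of all other genes (Fisher's exact test, adjusted p = 0.017). Fisher's exact test of the highest class against all other genes gave an odds ratio of 1.42 (adjusted p = 1.5e-07 over 10 classes of expression, exon number and length), with genes treated as independent, which they are not. The direction also differed between levels: in the class from 4.42 to 20.3 CPM, 200 genes rose and 118 fell (Fisher's exact test against all other called genes, adjusted p = 0.011). The highest class was split nearly evenly, with 196 higher and 205 lower. Its share of higher genes was below that of all other called genes (same test, adjusted p = 0.011). Genes with 1 annotated exon range were called less often (50 of 1197, 4.18%) than genes with several (1225 of 13850, 8.84%; Fisher's exact test, adjusted p = 6.9e-09). Genes of the shortest exonic length (up to 1362 bp) were called in 5.16% of cases (Fisher's exact test, adjusted p = 1.3e-17). The median absolute log2 fold change of called genes was 0.96 in the lowest expression class and 0.34 in the highest. Smaller changes were thus called at high counts. Exon number and length were not adjusted for expression, so these shares do not show which kinds of genes respond more. The share of genes called ranged from 6.01% on chromosome 15 to 11% on chromosome 13, and none of 19 chromosomes differed from the rest after adjustment (Fisher's exact test, smallest adjusted p = 0.369).

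The authors' deposited table gives their own comparison of the same groups. It holds 15284 genes, of which 1672 had an adjusted p below 0.05, 918 higher and 754 lower after water restriction. Of the 1275 genes called by edgeR, 1260 (98.8%) were also called in the authors' deposited table, all in the same direction. A further 412 genes were called in the authors' deposited table only and 15 by edgeR only. Across the 15044 genes in both, Pearson's r of the log2 fold changes was 0.99996, across genes and not replicates. A DESeq2 fit of the counts with the groups of the titles gave the log2 fold changes of the authors' deposited table for every gene within 1e-06. The fit with the libraries numbered 6 exchanged gave r = 0.793 with that table across genes, so the deposited comparison was made with the groups as titled.

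Part of the genome held no measurement. None of the 2817 annotated genes (8.63% of the table) on chromosome 19 beyond position 39670909, or on chromosomes 20, X, Y and MT, had a fragment in any library. These comprise 300 genes on chromosome 19, the next of which starts at 40855433, 938 on chromosome 20, 1494 on X, 48 on Y and 37 on MT. Before that position 422 of 529 genes (79.8%) on chromosome 19 had fragments, and on chromosomes 1 to 18 the share was 66.0% to 80.8%. X-linked genes, among them the gene of the vasopressin V2 receptor that mediates water reabsorption in the collecting duct, and the mitochondrially encoded genes of the respiratory chain were therefore not compared here.

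**Figure D4:**
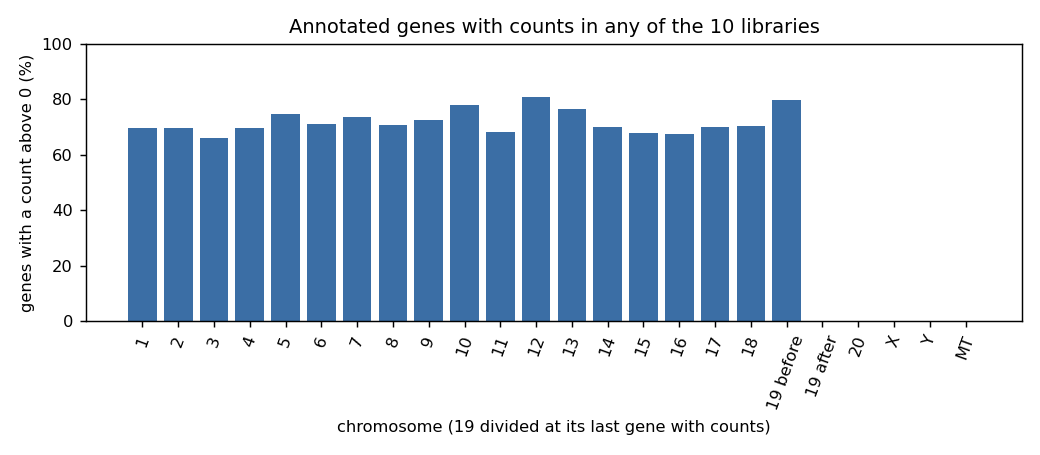
Share of annotated genes with at least 1 fragment in any of the 10 libraries, in percent, for each chromosome; chromosome 19 is divided at its last gene with fragments. The bars lie between 66.0% and 80.8% for chromosomes 1 to 18 and at 79.8% for the first part of chromosome 19, and are at 0 for all that follows.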

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

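The tests of the genes without counts and of the replicate 6 labels were chosen after the data were seen. The test of other splits was planned.

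Of 100 splits of the 10 libraries into groups of 5 (of 126 possible), 1, the real one, gave as many changed genes: it gave 1275, and the highest count of any other split was 3. The other splits each mixed control and dehydrated libraries, which adds the treatment difference to the spread within groups by construction. Their low counts therefore do not show how many genes would be called without a treatment difference. That only 1 of 100 splits reached 1275 argues against chance assignment of the libraries at the level these splits allow, but does not exclude it.

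The kidney of dehydrated replicate 5 had 13 CPM of ENSRNOG00000015992, while the other dehydrated kidneys had 5.83 to 7.70 CPM; its gap to the nearest kidney was large against the range of the group. Among the 18 sets of 5 values examined in this way, this was the only one with such a gap, and about 1 in 20 sets would show one by chance.

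Genes on the end of chromosome 19 and on chromosomes 20, X, Y and MT had no counts. Low expression is argued against by 0 of 2817 genes there having a count in any library, while 66.0% or more did on each of chromosomes 1 to 18. A reference or an alignment that ended inside chromosome 19 remains a candidate explanation: up to the last gene with counts 79.8% of the genes on chromosome 19 had counts, as did 21 of the 22 genes nearest to that point, and none after it. The genes without counts include all 938 on chromosome 20, all 1494 on X and all 37 on MT, in every library of both groups. An absence this complete beyond a single position argues against a biological cause for these genes. Apart from low expression no biological explanation was tested, and the sources used here do not record a cause.

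The libraries numbered 6 could have exchanged group labels, since their names carry the other group's letter. On the 896 genes called from the other 8 libraries, a score of -1 stands for the control mean and 1 for the dehydrated mean. Control replicate 6 scored -0.879 and dehydrated replicate 6 scored 0.937, among other controls at -1.12 to -0.468 and other dehydrated libraries at 0.513 to 1.13, each left out in the same way. These values argue against exchanged labels. In the authors' deposited table, column Rn6C holds the counts of control replicate 6 and column Rn6D those of dehydrated replicate 6. The letters of these columns thus follow the titled groups and differ from the library names. Such a pattern goes with an error in the names of the libraries rather than in their groups. How the names came to differ was not tested.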

How the results depend on the processing

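All 4 named genes kept their direction and their call under the 16 settings that keep the titled groups, with log2 fold changes of 3.12 to 3.63 for ENSRNOG00000015992, 3.06 to 3.48 for ENSRNOG00000003616, -6.02 to -5.59 for ENSRNOG00000013552 and -2.90 to -2.39 for ENSRNOG00000008915. Their adjusted p was at most 0.0009. With the libraries numbered 6 exchanged, edgeR gave 1.95, 1.64, -1.28 and -0.65 (adjusted p of 0.388 or more), DESeq2 1.92, 1.62, -1.28 and -0.65 (0.347 or more) and limma voom 2.81, 2.80, -4.84 and -1.78 (0.079 to 0.141). None of the 4 was called in these 3 fits, which mix the treatments within groups if the titled groups are right.

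The count of 1275 changed genes (707 higher, 568 lower) stayed within 1.5 times with DESeq2 size factors (1277), no filter on low counts (1244), limma voom (1491), the DESeq2 Wald test (1658) and an adjusted p below 0.1 (1837). Leaving out 1 library gave 879 (without dehydrated replicate 2) to 1382 changed genes (without control replicate 5), 485 to 763 higher and 378 (without control replicate 4) to 619 lower; 735 genes were called with all libraries and in each of these 10 fits. More than 2-fold changes numbered 213 (113 higher, 100 lower). Without both libraries numbered 6, 896 genes were called (461 higher, 435 lower), 806 of them among the 1275, in a fit with fewer libraries. Exchanging these 2 libraries left 0 changed, 0 higher and 0 lower genes in edgeR, with 1654 at an unadjusted p below 0.05. The exchange, added after the data were seen for the other tools, gave 71 (28 higher, 43 lower) in DESeq2 and 3 (1 higher, 2 lower) in limma. An exchange of 2 libraries adds the treatment difference to the spread within groups by construction.

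With the replicate number as a block, 763 genes were called (426 higher, 337 lower), with 59 same-direction neighbours. Same-numbered libraries deviated together with r of -0.057 to 0.15, and differently numbered ones with r of -0.15 to 0.10. Of the same-numbered pairs 1 of 4 exceeded 0.1, and 1 of 4 numbers correlated best with its own partner. The labels do not say what the numbers mean, and 4 correlations cannot settle it. Control replicate 3 and dehydrated replicate 1 have no partner, so the block fit rests on 4 pairs.

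The 2817 genes without counts on the end of chromosome 19 and on chromosomes 20, X, Y and MT were tested under none of these settings. The planned lists were not run under any setting, since no identifier is paired with a symbol.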

Other observations

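The tests of neighbouring genes and of the spread between animals were written before their results were seen; the gene groups by position were picked afterwards. Some of the genes that changed in the same direction were neighbours along the chromosomes. Among 15028 pairs of neighbouring tested genes, 163 pairs had both genes called, 116 in the same direction and 47 in opposite directions. In 15 places at least 3 consecutive tested genes changed the same way (8 higher, 7 lower, 49 genes in all). On chromosome 1, 4 consecutive genes between 263968134 and 264172729 fell, the last of them ENSRNOG00000013552. The gene at 264059374 to 264072433 fell from 194 ± 64.7 to 70.4 ± 19.7 CPM (SD, n = 5), and the first of the group, at 263968134, from 1.48 ± 0.566 to 0.097 ± 0.046 CPM (SD, n = 5). On chromosome 3 the abundant gene at 171213936, which rose to 5846 CPM, lay between 2 low genes that also rose. The one on the opposite strand at 171145584 went from 0.689 ± 0.170 to 3.38 ± 1.35 CPM, and the one on the same strand at 171242108 from 0.984 ± 0.182 to 2.66 ± 0.855 CPM (SD, n = 5).

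The count of 116 same-direction neighbours was 2.11 times the mean of 55.0 under permutation, while the 47 opposite-direction neighbours showed no excess (mean 53.4, with as many in a share of 0.83 of the permutations). Calls were permuted within chromosome and expression decile, and none of the 10000 permutations reached the observed count. With the observed count included, the share was 1e-04, the smallest they can give. Like expression level of neighbours is therefore argued against as the whole cause. Transcription reading on into the next gene on the same strand is argued against as the whole cause by 47 pairs on opposite strands, against 28.9 permuted (central 95% up to 40). Pairs of unlike exonic length numbered 68, against 36.9 permuted (central 95% up to 49), so the excess was not limited to pairs of like length. Exonic length does not measure shared sequence or shared reads, so tandem copies that share reads stay open as a cause. Pairs on the same strand (69 against 26.0 permuted) and close pairs of like length (39 against 12.5) were also in excess. Reading on and tandem copies may therefore still contribute there. Whether the excess differed between these kinds of pairs was not tested. Shared regulation of neighbouring genes by water restriction remains a hypothesis; the same-direction count was 72 without control replicate 4, 70 without dehydrated replicate 2, 70 without both libraries numbered 6, and 0 with these exchanged in edgeR, where fewer genes were called. It was 212 at an adjusted p below 0.1, where more genes were called, and 12 among genes changed more than 2-fold, where fewer were. The permutation was not repeated under these settings, so the counts do not show whether the excess became larger or smaller.

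A further hypothesis was that water restriction changes the spread between animals. The median SD of log2 CPM over tested genes was 0.129 in control and 0.129 in dehydrated kidneys, a ratio of 1.00 (exact permutation p = 0.992 over all reassignments of group-centred values, n = 5 per group). No difference in spread was detected.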
